A study of Mus musculus with 24 samples.

How the data were processed

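The series holds 24 RNA-seq libraries from mouse CD8+ T cells activated in vitro, 3 per group in 8 groups: control, LCA, IsoLCA, IsoAlloLCA, DehydroLCA and UDCA at 50 µM, and TCA and TCDCA at 100 µM. Exposure lasted 24 h per the series' design text, while the treatment protocol in the labels gives it as overnight. Total RNA was isolated with a column kit and made into cDNA libraries with a method for very low input, per the labels' protocols. Groups and replicate numbers were taken from the sample titles.

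The authors deposited 1 table of 24537 genes, each represented by 1 RefSeq transcript, made with HOMER by counting reads over exons on the mm10 genome without normalization, per the file headers. The submitters' processing notes also name STAR, DESeq2 and the GRCm38 build, without versions. The header names no strand option. The deposited values are expected counts in steps of 0.5 (29.43% are not whole), as arise when reads are divided between features, and were rounded to whole counts before testing, upward where a value ended in 0.5. The design fixed before the data were examined had assumed whole counts. The same count test was used. Reads from near-identical paralogs (such as Mt1 and Mt2, Abcb1a and Abcb1b, or Selenbp1 and Selenbp2), from the 393 genes with more than 1 copy in the table, and from overlapping or antisense genes may have been divided between them or mixed, so these values are uncertain. The table holds 0 genes of the mitochondrial chromosome.

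Counts in genes ran from 25998051 to 41024340.5 per library (median 32852325). Counts in exons made up 75.6% to 84.7% of the library totals given in the file headers, and the ribosomal RNA gene Rn45s took 0.628% to 1.56% of counts. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom of 2.75 to 17.8 between pairs, so no library was counted as a duplicate.

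Counts were analysed in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit and test, glmQLFit and glmQLFTest). The 24 libraries were fitted together with 1 coefficient per group and no block, so that groups share an estimate of the spread. Normalization was by TMM (factors 0.971 to 1.05) and filterByExpr kept 13044 genes. The common biological coefficient of variation was 4.41%, on 16 residual degrees of freedom and 8.84 prior degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the tested genes of a comparison were called changed. Each bile acid was compared with control, and 5 pairs of related acids given at the same dose were compared directly: IsoLCA with LCA, IsoAlloLCA with IsoLCA, DehydroLCA with LCA, UDCA with LCA, and TCA with TCDCA. The SE of a log2 fold change was its absolute value divided by the square root of the quasi-likelihood F statistic. It thus rests on a spread estimated over the 24 libraries and moderated across genes, not on the 6 libraries of a comparison alone. The 95% intervals of the log2 fold change were built from this SE.

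Before the data were examined, 27 gene lists were fixed, covering T cell function, stress responses, lipid and energy metabolism, cell cycle and death, interferon response and markers of other cell types. The 24 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison. Lists of mitochondrially encoded genes, of B cell genes and of stromal and erythroid genes had too few tested members. Some lists share members, such as Scd1 and Srebf1 in the liver X receptor and fatty acid synthesis lists. Calls of such lists are not independent. Members were counted over all genes tested and adjusted over the list alone. Genes named in the text follow a rule also fixed in advance: for each acid against control the 5 largest rises and 5 largest falls among called genes with a mean of at least 10 CPM in a group, no overlap between the libraries of the groups and an established symbol, the 4 members with the smallest adjusted p in each called list, and a fixed set of T cell, stress and lipid genes. For pairs of acids 4 rises, 4 falls and 3 members were taken. Il2 and Cyp24a1 of the fixed set reached at most 2 and 1 counts in a library and were not tested. Some genes that the rule names are not reported here.

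Likeness of responses was measured by the correlation and covariance of log2 fold changes over tested genes, beside 20 simulations of unchanged groups against the same controls. The fit was tested on simulated counts of 13044 genes, drawn from the control means at the sizes of the 24 libraries. Set genes were changed in the LCA group. Of these, 40% of 100 genes changed 1.2-fold and 74% of 100 genes changed 1.5-fold were called. Unchanged genes made up 5.88% of the calls, and the slope of estimated on true log2 fold change was 0.984. The 1 list that had been changed was called. Its 17 members were each raised 1.2-fold and genes were drawn independently, so this call was likely in advance. It cannot show whether the preset correlation of camera suits the real data. For UDCA and TCDCA, a simulated shared covariance of 0.0393 was recovered as 0.0387.

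Other settings fixed before the data were examined were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test (1.42.0), a fit on the 6 libraries of a comparison, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation and fry. Chosen after seeing the data were thinning every library to the smallest total, correcting each library for its trend on GC content and transcript length (99.5% of tested genes had values), and the share of reads in exons as a covariate. For each comparison the 10 ways of dividing its 6 libraries into 3 and 3 were refitted.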

Results

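RNA-seq libraries were made from mouse CD8+ T cells that had been activated in culture and then exposed to a bile acid, in a series on how bile acid synthesis bears on T cell responses to liver tumours. The design has 8 groups of 3 libraries: untreated control cells and cells given lithocholic acid (LCA), isolithocholic acid (IsoLCA), isoallolithocholic acid (IsoAlloLCA), dehydrolithocholic acid (DehydroLCA), ursodeoxycholic acid (UDCA), taurocholic acid (TCA) or taurochenodeoxycholic acid (TCDCA). The unconjugated acids were given at 50 µM and the taurine conjugates TCA and TCDCA at 100 µM, so the conjugated and unconjugated acids differ in dose as well as in structure. The labels do not say whether libraries of a group came from separate animals or cultures, and the p-values then measure only the spread between these samples, which may be technical.

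The libraries held 25998051 to 41024340.5 counts in genes, with a median of 32852325, and 13044 genes had enough counts to be tested. The share of each library's total that lay in exons ran from 75.6% to 84.7%. It was lowest on average in IsoAlloLCA (78.3% ± 2.78, SD, n = 3) against 82.6% ± 1.37 (SD, n = 3) in control, and each IsoAlloLCA result below goes with that difference. Across the tested genes, the first principal component held 38.4% of the variance and set the IsoAlloLCA libraries apart, and the second held 12% and had the LCA libraries at its low end. In what follows, values after gene names are edgeR log2 fold changes ± SE, comparing 3 libraries with 3. The SE was derived from the test statistic, with a spread estimated over the 24 libraries. It need not follow the spread within the groups compared. Levels are mean ± SD CPM, counts scaled to library size (n = 3), and "rose" and "fell" are used of genes that passed the test. Counts for a gene list are of its tested members. Genes named as the largest rises, falls or differences are the largest among ranked genes only. Ranked genes were called, had an established symbol and at least 10 CPM in a group, and did not overlap between the groups' libraries. Larger changes in other genes, such as Grin1 with TCDCA (-4.56, 1.54 CPM in control), are outside these rankings. Coordinates are those of the deposited table, on the mm10 mouse genome.

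**Figure D1:**
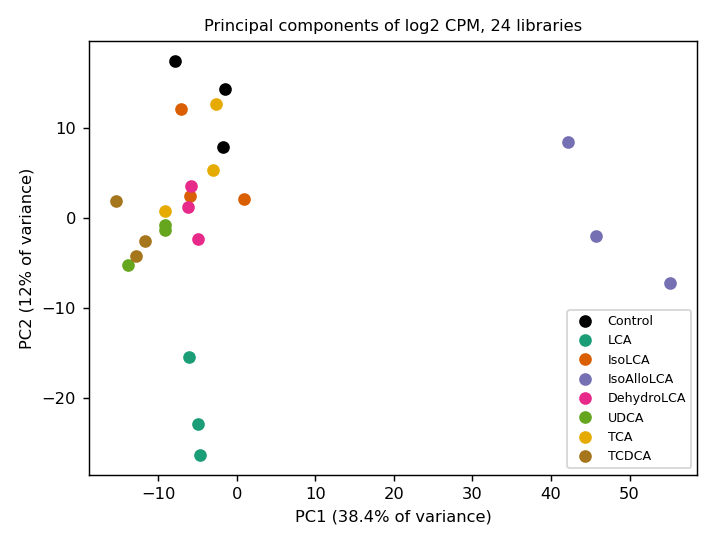
Scores of the 24 libraries on the first and second principal components of log2 CPM over the tested genes, 1 point per library, coloured by group. The axis labels give the share of variance, 38.4% and 12%, and the 3 IsoAlloLCA libraries lie apart from the other 21 on the first.

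The question put to each bile acid was how its presence altered gene expression in activated CD8+ T cells. The number of changed genes differed widely, from 57 with TCA to 7618 with IsoAlloLCA, and changes beyond 2-fold were fewer, from 1 with TCA to 739 with IsoAlloLCA. Glycolysis and hypoxia-responsive genes were called lower as a list in each of the 7 comparisons with control, though with an estimated correlation the call was lost for IsoLCA (adjusted p = 0.0699), IsoAlloLCA (0.556) and DehydroLCA (0.097). The cholesterol synthesis list was called lower with the 5 unconjugated acids and higher with TCA, and with an estimated correlation this held for LCA, IsoAlloLCA and UDCA and was lost for IsoLCA (0.282), DehydroLCA (0.0628) and TCA (0.172).

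**Figure D2:**
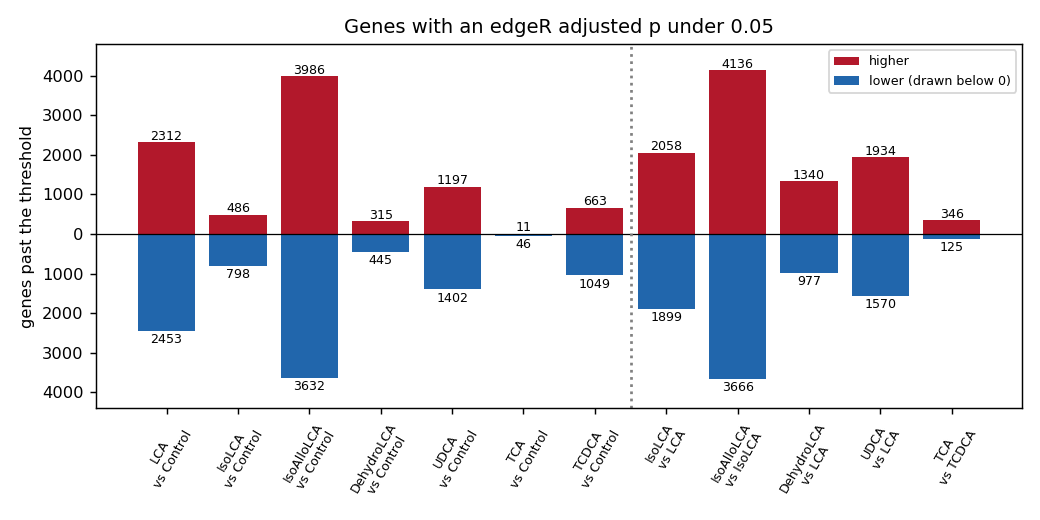
Number of genes called higher and lower (edgeR adjusted p under 0.05) in each comparison. The bile acid groups against control come first, followed by the pairs of related acids. Against control the totals run from 57 genes with TCA to 7618 with IsoAlloLCA. Among the pairs they run from 471 for TCA against TCDCA to 7802 for IsoAlloLCA against IsoLCA. The split of calls between directions is given for each comparison in the text.

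**Figure D3:**
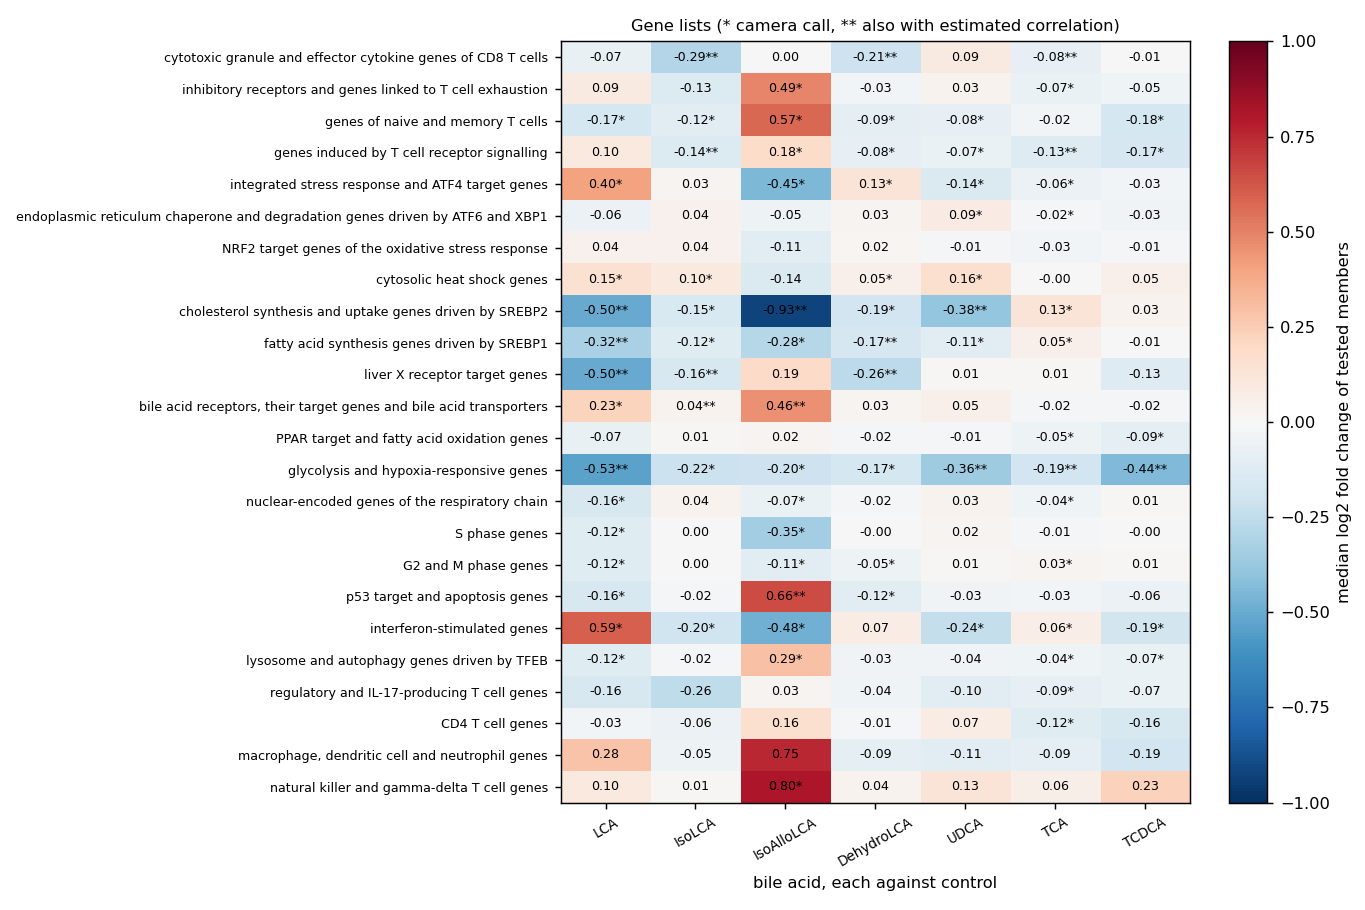
Median log2 fold change of the tested members of each of the 24 gene lists (vertical axis) in each bile acid group against control (horizontal axis), as colour and printed value. A star marks a camera call and a pair of stars a call that also holds with an estimated correlation. Glycolysis and hypoxia-responsive genes have medians between -0.53 and -0.17 in the 7 groups.

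LCA lowered lipid synthesis and glycolysis genes. Stress response and interferon lists were called higher, calls lost with an estimated correlation (adjusted p = 0.0729 and 0.113). Among cholesterol synthesis genes, 25 of 27 fell and 2 did not pass (26 adjusted over the list alone), camera adjusted p = 3.12e-36. Examples are Hmgcs1, an early enzyme of the pathway (-0.77 ± 0.06), Acat2 (-0.72 ± 0.05) and Dhcr7 (-0.69 ± 0.05). Of the fatty acid synthesis genes, 2 of 18 rose, 11 fell and 5 did not pass (2 and 11 adjusted over the list alone), camera adjusted p = 2.53e-11, including the desaturases Scd1 (-1.72 ± 0.10) and Scd2 (-0.92 ± 0.05). Among liver X receptor targets, 8 of 12 fell and 4 did not pass (8 adjusted over the list alone), camera adjusted p = 4.37e-12. Of those named, the sterol exporters Abcg1 (-1.96 ± 0.09) and Abca1 (-1.98 ± 0.29) fell most strongly. Abcg1 (chromosome 17, 31057694 to 31117981, plus strand) went from 27.6 ± 0.469 to 7.04 ± 1.17 CPM. Abca1 was scarce, at 0.86 ± 0.14 CPM in control and 0.21 ± 0.03 CPM in LCA. Genes of glycolysis and the hypoxia response fell together: 1 of 29 rose, 25 fell and 3 did not pass (1 and 25 adjusted over the list alone), camera adjusted p = 3.61e-35, led by Slc16a3 (-1.08 ± 0.06), a lactate exporter, and Pgk1 (-0.77 ± 0.05). The hypoxia-linked genes Aldoc (-2.05 ± 0.12) and P4ha2 (-1.99 ± 0.19) showed the largest falls among genes of at least 10 CPM whose libraries did not overlap between the groups. Of nuclear-encoded respiratory chain genes, 47 of 74 fell and 27 did not pass (51 adjusted over the list alone), camera adjusted p = 1.11e-09, and adjusted p = 0.40 with an estimated correlation, by a median of -0.16.

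The largest rises with LCA were in Cth, an enzyme of cysteine synthesis (chromosome 3, 157894248 to 157925063, minus strand; from 4.21 ± 0.817 to 14.9 ± 2.28 CPM, 1.81 ± 0.17, edgeR adjusted p = 4.97e-09), the interferon-induced Rtp4 (1.57 ± 0.15), the invariant chain gene Cd74 (1.47 ± 0.10), the nuclear lamina gene Lmna (1.43 ± 0.07) and Kcnq1ot1 (from 8.98 ± 3.07 to 23.4 ± 7.45 CPM, 1.39 ± 0.32), a noncoding RNA antisense to Kcnq1; the strand option of the counting is not given in the sources used here. Among integrated stress response and ATF4 target genes 31 of 39 rose, 2 fell and 6 did not pass (32 and 2 adjusted over the list alone), camera adjusted p = 1.19e-20, and adjusted p = 0.0729 with an estimated correlation. Atf5 (1.16 ± 0.08), the amino acid transporter Slc7a3 (1.14 ± 0.10) and the pseudokinase Trib3 (0.83 ± 0.07) rose. Of the interferon-stimulated genes 20 of 33 rose, 6 fell and 7 did not pass (21 and 7 adjusted over the list alone), camera adjusted p = 7.78e-08, and adjusted p = 0.113 with an estimated correlation. Oasl1 (1.72 ± 0.14) and Isg15 (1.39 ± 0.13) rose. Cytosolic heat shock genes also moved up: 9 of 17 rose and 8 did not pass (9 adjusted over the list alone), camera adjusted p = 0.000256, and adjusted p = 0.183 with an estimated correlation. Naive and memory T cell genes went down: 1 of 24 rose, 11 fell and 12 did not pass (1 and 11 adjusted over the list alone), camera adjusted p = 5.00e-05, and adjusted p = 0.183 with an estimated correlation. The transcription factor gene Klf2 (-1.32 ± 0.16) fell. The cytotoxic effector genes Gzmb (-0.40 ± 0.09) and Prf1 (-0.76 ± 0.11) fell, while values for Ifng (0.06 ± 0.17) and Pdcd1 (0.08 ± 0.09) did not pass the test. Cell cycle genes were lower. In S phase, 17 of 30 fell and 13 did not pass (1 rose and 17 fell adjusted over the list alone), camera adjusted p = 0.00177, and adjusted p = 0.489 with an estimated correlation. In G2 and M phase, 21 of 32 fell and 11 did not pass (21 adjusted over the list alone), camera adjusted p = 6.34e-05, and adjusted p = 0.316 with an estimated correlation. Among p53 target and apoptosis genes, 2 of 24 rose, 13 fell and 9 did not pass (2 and 13 adjusted over the list alone), camera adjusted p = 0.000245, and adjusted p = 0.0729 with an estimated correlation. Bile acid receptor, target and transporter genes were higher: 5 of 11 rose and 6 did not pass (5 adjusted over the list alone), camera adjusted p = 0.024, and adjusted p = 0.0729 with an estimated correlation. Lysosome and autophagy genes were lower: 6 of 32 rose, 14 fell and 12 did not pass (6 and 14 adjusted over the list alone), camera adjusted p = 0.00177, and adjusted p = 0.263 with an estimated correlation. In all, 4765 of 13044 tested genes changed, 2312 higher and 2453 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05).

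IsoLCA lowered effector and activation genes and raised, most of all ranked genes, the metallothionein genes and Lmna, a gene of the nuclear lamina. Of the cytotoxic effector list 3 of 27 rose, 10 fell and 14 did not pass (3 and 13 adjusted over the list alone), camera adjusted p = 1.17e-06. The scarce chemokine genes Ccl3 (from 2.09 ± 0.24 to 0.56 ± 0.16 CPM, -1.89 ± 0.20) and Ccl4 (from 2.21 ± 0.14 to 0.69 ± 0.17 CPM, -1.65 ± 0.18) fell. The transcription factor gene Prdm1 (-0.77 ± 0.06) fell too. Among genes induced by T cell receptor signalling 11 of 27 fell and 16 did not pass (12 adjusted over the list alone), camera adjusted p = 1.86e-08. Egr3 (-1.01 ± 0.11) and Irf4 (-0.66 ± 0.04) fell. The largest rises were in the metallothionein genes Mt2 (chromosome 8, 94172618 to 94173567, plus strand; from 66.4 ± 5.01 to 236 ± 10.2 CPM, 1.83 ± 0.07, edgeR adjusted p = 1.75e-15) and Mt1 (1.33 ± 0.06), close relatives that could share reads, and in Lmna (1.77 ± 0.06) and Unc5b (1.18 ± 0.21) and the nuclear receptor gene Rxra (1.09 ± 0.07). The largest falls of ranked genes were in Acp5 (-1.80 ± 0.08), Bspry (-1.49 ± 0.09), Tubb6 (-1.38 ± 0.07), Treml2 (-1.27 ± 0.04) and Gfi1 (-1.22 ± 0.07).

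Of the bile acid receptor, target and transporter genes 4 of 11 rose and 7 did not pass (4 rose and 1 fell adjusted over the list alone), camera adjusted p = 0.00203. The list holds 29 genes, of which only these 11 could be tested. Those that rose were Rxra, the scarce Vdr (3.80 ± 0.51 CPM with IsoLCA, 0.51 ± 0.15), Abcb1a (0.22 ± 0.06) and Abcb1b (0.26 ± 0.03). Abcb1a and Abcb1b are paralogs that could share reads. Lipid genes went the other way: among liver X receptor targets 3 of 12 fell and 9 did not pass (4 adjusted over the list alone), camera adjusted p = 0.000155. Abcg1 (-0.89 ± 0.08) and Scd1 (-0.75 ± 0.10) fell, Scd1 also counting in the fatty acid synthesis list below. Among cholesterol synthesis genes 13 of 27 fell and 14 did not pass (16 adjusted over the list alone), camera adjusted p = 8.98e-08, and adjusted p = 0.282 with an estimated correlation. Of the fatty acid synthesis genes 5 of 18 fell and 13 did not pass (1 rose and 8 fell adjusted over the list alone), camera adjusted p = 0.00238, and adjusted p = 0.309 with an estimated correlation. Glycolysis and hypoxia-responsive genes were lower: 21 of 29 fell and 8 did not pass (23 adjusted over the list alone), camera adjusted p = 3.19e-20, and adjusted p = 0.0699 with an estimated correlation. The glucose transporter gene Slc2a3 (-0.77 ± 0.09) was one of them. Interferon-stimulated genes were also lower: 9 of 33 fell and 24 did not pass (14 adjusted over the list alone), camera adjusted p = 9.43e-08, and adjusted p = 0.143 with an estimated correlation. Gbp2 (-0.71 ± 0.06) and Irf1 (-0.50 ± 0.04) fell. Naive and memory genes were lower as well: 2 of 24 rose, 10 fell and 12 did not pass (2 and 11 adjusted over the list alone), camera adjusted p = 0.00115, and adjusted p = 0.309 with an estimated correlation. Klf2 (-0.74 ± 0.15) fell. Cytosolic heat shock genes were higher: 4 of 17 rose and 13 did not pass (5 adjusted over the list alone), camera adjusted p = 0.00146, and adjusted p = 0.282 with an estimated correlation. In all, 1284 of 13044 tested genes changed, 486 higher and 798 lower (edgeR). Without control replicate 2 the count was 815. After correction for GC content and transcript length, chosen after seeing the data, the split was 690 higher and 665 lower.

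IsoAlloLCA changed 58.4% of the tested genes and raised p53 target and apoptosis genes while lowering cholesterol synthesis genes. Of the p53 target and apoptosis genes 19 of 24 rose, 3 fell and 2 did not pass (20 and 4 adjusted over the list alone), camera adjusted p = 6.66e-14. They include Bbc3 (chromosome 7, 16309583 to 16318334, plus strand; from 15 ± 0.627 to 47.6 ± 5.14 CPM, 1.67 ± 0.08, edgeR adjusted p = 8.59e-15) and Bcl2l11 (1.62 ± 0.09), Fas (1.45 ± 0.08) and Pmaip1 (0.94 ± 0.05), all promoters of cell death, and the cell cycle inhibitor Cdkn1a (0.88 ± 0.07). Among cholesterol synthesis genes 25 of 27 fell and 2 did not pass (25 adjusted over the list alone), camera adjusted p = 3.36e-33, led by Fdps (-1.33 ± 0.06) and Hmgcs1 (chromosome 13, 119690351 to 119708260, plus strand; from 432 ± 18.9 to 174 ± 11.9 CPM, -1.31 ± 0.06). Of the bile acid receptor, target and transporter genes 6 of 11 rose, 1 fell and 4 did not pass (6 and 1 adjusted over the list alone), camera adjusted p = 6.49e-05, with the paralogous efflux pump genes Abcb1a (1.25 ± 0.06) and Abcb1b (1.22 ± 0.03), which could share reads. Of ranked genes, Lmna rose most, from 6.97 ± 0.444 to 67.2 ± 1.39 CPM (3.27 ± 0.06, chromosome 3, 88481148 to 88503352, minus strand). Cd83 rose from 2.06 ± 0.448 to 16.6 ± 3.31 CPM (3.03 ± 0.15, chromosome 13, 43785112 to 43803133, plus strand). Tnfsf4 (2.81 ± 0.11), Rgs2 (2.65 ± 0.17) and Ttc39c (2.55 ± 0.13) came next. The largest falls of ranked genes with IsoAlloLCA were in Tnfrsf8 (-2.73 ± 0.13), Bspry (-2.18 ± 0.10), Treml2 (-2.12 ± 0.04), Lif (-2.07 ± 0.14) and Scd1 (-2.06 ± 0.11).

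Naive and memory T cell genes rose with IsoAlloLCA: 14 of 24 rose, 5 fell and 5 did not pass (14 and 5 adjusted over the list alone), camera adjusted p = 0.00151, and adjusted p = 0.322 with an estimated correlation. The transcription factor gene Tcf7 rose from 118 ± 2.71 to 338 ± 40 CPM (1.52 ± 0.13), and Ccr7 (1.19 ± 0.08) and the interleukin 7 receptor gene Il7r (0.98 ± 0.05) rose as well. Of the inhibitory receptor list 11 of 18 rose, 3 fell and 4 did not pass (12 and 3 adjusted over the list alone), camera adjusted p = 0.00377, and adjusted p = 0.124 with an estimated correlation. Havcr2 (0.92 ± 0.08), Tigit (0.93 ± 0.08), Pdcd1 (0.57 ± 0.09) and Lag3 (0.60 ± 0.07) rose. Among T cell receptor-induced genes 15 of 27 rose, 7 fell and 5 did not pass (15 and 7 adjusted over the list alone), camera adjusted p = 0.00103, and adjusted p = 0.182 with an estimated correlation. Cd69 (1.49 ± 0.06) and Nr4a1 (1.21 ± 0.07) rose. The granule genes Gzmb (chromosome 14, 56258836 to 56262334, minus strand; from 3784 ± 230.0 to 2245 ± 359 CPM, -0.75 ± 0.09) and Prf1 (-0.58 ± 0.11) fell.

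Integrated stress response and ATF4 target genes were lower with IsoAlloLCA: 4 of 39 rose, 30 fell and 5 did not pass (4 and 30 adjusted over the list alone), camera adjusted p = 1.07e-09, and adjusted p = 0.262 with an estimated correlation. Slc7a5 (-0.84 ± 0.06) and Trib3 (-0.54 ± 0.08) fell, although Atf3 (0.74 ± 0.11) and Ddit3 (0.40 ± 0.09) rose. Interferon-stimulated genes were lower as well: 4 of 33 rose, 23 fell and 6 did not pass (4 and 23 adjusted over the list alone), camera adjusted p = 0.00151, and adjusted p = 0.372 with an estimated correlation. Of the S phase genes 29 of 30 fell and 1 did not pass (29 adjusted over the list alone), camera adjusted p = 6.76e-14, and adjusted p = 0.124 with an estimated correlation. Mcm2 (-0.59 ± 0.04) and Ccne1 (-0.65 ± 0.05) fell. Of the G2 and M phase genes 3 of 32 rose, 20 fell and 9 did not pass (3 and 20 adjusted over the list alone), camera adjusted p = 0.00423, and adjusted p = 0.48 with an estimated correlation. Lysosome and autophagy genes were higher: 23 of 32 rose, 1 fell and 8 did not pass (23 and 1 adjusted over the list alone), camera adjusted p = 7.03e-05, and adjusted p = 0.151 with an estimated correlation. Metabolic lists were lower as well. Of the fatty acid synthesis genes 1 of 18 rose, 14 fell and 3 did not pass (1 and 14 adjusted over the list alone), camera adjusted p = 9.51e-07, and adjusted p = 0.124 with an estimated correlation, and of the glycolysis genes 1 of 29 rose, 19 fell and 9 did not pass (1 and 19 adjusted over the list alone), camera adjusted p = 0.00423, and adjusted p = 0.556 with an estimated correlation.

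Natural killer and gamma-delta T cell genes rose with IsoAlloLCA: 6 of 9 rose, 1 fell and 2 did not pass (6 and 1 adjusted over the list alone), camera adjusted p = 0.0486, and adjusted p = 0.133 with an estimated correlation. Klrk1 (0.65 ± 0.04) and Klre1 (1.32 ± 0.15) rose. That call was lost without control replicate 2 (adjusted p = 0.0603) or IsoAlloLCA replicate 2 (0.0687), with values from 1.61e-09 to 0.133 over the alternatives. Respiratory chain genes were lower: 5 of 74 rose, 27 fell and 42 did not pass (5 and 25 adjusted over the list alone), camera adjusted p = 0.0272, and adjusted p = 0.70 with an estimated correlation. The list was not called without control replicate 3 (adjusted p = 0.114) or IsoAlloLCA replicate 2 (0.171), with values from 0.00169 to 0.70 over the alternatives. In all, 7618 of 13044 tested genes changed, 3986 higher and 3632 lower (edgeR). After the GC content and length correction the split was 3026 higher and 4739 lower. It was 3683 and 3900 with DESeq2 size factors, and 3442 and 3790 with the DESeq2 Wald test. With no filter on low counts it was 3738 and 3752, and with thinned libraries 3619 and 3643. More genes were higher with the replicate block, on the 6 libraries alone and with the share of reads in exons as a covariate. The balance of rises and falls therefore depends on such choices.

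DehydroLCA lowered liver X receptor target, fatty acid synthesis and effector genes. Of the liver X receptor targets 7 of 12 fell and 5 did not pass (8 adjusted over the list alone), camera adjusted p = 6.99e-17. The scarce Abca1 (0.86 ± 0.14 CPM in control, -2.30 ± 0.32) and Abcg1 (-1.44 ± 0.09) fell, Abcg1 from 27.6 ± 0.469 to 10.1 ± 1.2 CPM (edgeR adjusted p = 5.62e-11). Among fatty acid synthesis genes 9 of 18 fell and 9 did not pass (1 rose and 12 fell adjusted over the list alone), camera adjusted p = 4.75e-11. Scd1 (-0.91 ± 0.10) and Scd2 (-0.53 ± 0.05) fell. Among cholesterol synthesis genes 16 of 27 fell and 11 did not pass (22 adjusted over the list alone), camera adjusted p = 3.34e-20, and adjusted p = 0.0628 with an estimated correlation. Of the effector list 3 of 27 rose, 7 fell and 17 did not pass (4 and 11 adjusted over the list alone), camera adjusted p = 7.60e-05. The scarce Ccl3 (0.63 ± 0.15 CPM with DehydroLCA, -1.72 ± 0.19) and Ccl4 (1.04 ± 0.04 CPM, -1.08 ± 0.17) fell, as did Prdm1 (-0.52 ± 0.06). The largest rises were in Unc5b (chromosome 10, 60762595 to 60831581, minus strand; from 4.48 ± 0.329 to 10.8 ± 5.2 CPM, 1.28 ± 0.21) and Lmna (1.09 ± 0.07), Rxra (0.83 ± 0.07), Mical2 (0.77 ± 0.12) and Rnf43 (0.66 ± 0.09). The Unc5b libraries were uneven, with a log2 fold change of 0.81 without DehydroLCA replicate 1 (adjusted p = 0.000908). Further falls were in Iigp1 (-0.88 ± 0.06), Acp5 (-0.86 ± 0.07) and Tg (-0.80 ± 0.10).

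With DehydroLCA, glycolysis and hypoxia-responsive genes were lower: 16 of 29 fell and 13 did not pass (23 adjusted over the list alone), camera adjusted p = 4.90e-17, and adjusted p = 0.097 with an estimated correlation. Egln3 (-0.45 ± 0.09) and Pgk1 (-0.26 ± 0.05) fell. Integrated stress response genes were higher: 6 of 39 rose, 2 fell and 31 did not pass (24 and 2 adjusted over the list alone), camera adjusted p = 1.09e-07, and adjusted p = 0.339 with an estimated correlation. Trib3 (0.38 ± 0.07) and Slc3a2 (0.21 ± 0.04) rose. Heat shock genes were higher as well: 4 of 17 rose and 13 did not pass (5 adjusted over the list alone), camera adjusted p = 0.000365, and adjusted p = 0.21 with an estimated correlation. Of the naive and memory genes, 4 of 24 fell and 20 did not pass (8 adjusted over the list alone), camera adjusted p = 0.000288, and adjusted p = 0.236 with an estimated correlation. Of the T cell receptor-induced genes, 2 of 27 fell and 25 did not pass (4 adjusted over the list alone), camera adjusted p = 0.00054, and adjusted p = 0.173 with an estimated correlation. Lists of p53 targets and of dividing cells were lower too. Among the p53 target genes, 4 of 24 fell and 20 did not pass (1 rose and 9 fell adjusted over the list alone), camera adjusted p = 0.00036, and adjusted p = 0.0861 with an estimated correlation. Among G2 and M phase genes, 1 of 32 fell and 31 did not pass (0 adjusted over the list alone), camera adjusted p = 0.00392, and adjusted p = 0.498 with an estimated correlation. In all, 760 of 13044 tested genes changed, 315 higher and 445 lower (edgeR). The count was 400 without control replicate 2, 426 without DehydroLCA replicate 1 and 460 without DehydroLCA replicate 3. It was 1355 with the share of reads in exons as a covariate, chosen after seeing the data.

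UDCA lowered glycolysis and cholesterol synthesis genes. Among glycolysis and hypoxia-responsive genes 26 of 29 fell and 3 did not pass (1 rose and 27 fell adjusted over the list alone), camera adjusted p = 2.27e-38: the glucose transporter gene Slc2a3 (chromosome 6, 122727809 to 122742745, minus strand) fell from 342 ± 41.8 to 178 ± 9.98 CPM (-0.94 ± 0.09, edgeR adjusted p = 6.44e-08), and Pgk1 (-0.59 ± 0.05) and Aldoa (-0.45 ± 0.04) fell with it. Of the cholesterol synthesis genes 23 of 27 fell and 4 did not pass (24 adjusted over the list alone), camera adjusted p = 6.09e-39. Hmgcs1 (-0.70 ± 0.06) and Insig1 (-0.68 ± 0.07) fell. Of the fatty acid synthesis genes 2 of 18 rose, 8 fell and 8 did not pass (3 and 9 adjusted over the list alone), camera adjusted p = 0.000344, and adjusted p = 0.336 with an estimated correlation. The largest falls of ranked genes were in the lipoprotein receptor gene Vldlr (-1.82 ± 0.23), the glycogen phosphorylase gene Pygl (-1.59 ± 0.20) and P4ha2 (-1.53 ± 0.18), Aldoc (-1.49 ± 0.12) and Gem (-1.21 ± 0.16). The largest rises were in Cd160 (0.86 ± 0.10), Egr3 (0.77 ± 0.09), Arrdc3 (0.68 ± 0.10) and Jdp2 (0.68 ± 0.10).

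Integrated stress response genes were lower with UDCA: 1 of 39 rose, 18 fell and 20 did not pass (1 and 20 adjusted over the list alone), camera adjusted p = 6.35e-10, and adjusted p = 0.353 with an estimated correlation. Trib3 (-0.67 ± 0.08), Ddit3 (-0.69 ± 0.10) and Atf3 (-0.87 ± 0.13) fell. Endoplasmic reticulum chaperone genes were higher: 14 of 34 rose, 2 fell and 18 did not pass (14 and 3 adjusted over the list alone), camera adjusted p = 0.00173, and adjusted p = 0.44 with an estimated correlation. Hspa5 (0.32 ± 0.05) and Calr (0.40 ± 0.04) rose. Cytosolic heat shock genes were higher too: 9 of 17 rose and 8 did not pass (9 adjusted over the list alone), camera adjusted p = 1.79e-05, and adjusted p = 0.22 with an estimated correlation. Interferon-stimulated genes were lower: 13 of 33 fell and 20 did not pass (13 adjusted over the list alone), camera adjusted p = 1.72e-05, and adjusted p = 0.336 with an estimated correlation. Among fixed T cell genes, Ifng (0.77 ± 0.16) rose and Prf1 (-0.55 ± 0.11) and Il7r (-0.52 ± 0.05) fell. Naive and memory genes were called lower: 7 of 24 fell and 17 did not pass (8 adjusted over the list alone), camera adjusted p = 0.00841, and adjusted p = 0.44 with an estimated correlation. That call was lost without UDCA replicate 3 (adjusted p = 0.274), with values from 0.000186 to 0.44 over the alternatives. T cell receptor-induced genes were called lower: 5 of 27 rose, 10 fell and 12 did not pass (5 and 10 adjusted over the list alone), camera adjusted p = 0.0202, and adjusted p = 0.422 with an estimated correlation. This call was lost without control replicate 2 (adjusted p = 0.0505) or UDCA replicate 2 (0.0684), with values from 0.00378 to 0.422 over the alternatives. In all, 2599 of 13044 tested genes changed, 1197 higher and 1402 lower (edgeR), or 1692 without control replicate 2. The split was 1621 higher and 1221 lower after the GC content and length correction. It was 2019 higher and 1791 lower with the share of reads in exons as a covariate.

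TCA at 100 µM changed few genes. Glycolysis and hypoxia-responsive genes were lower: 6 of 29 fell and 23 did not pass (26 adjusted over the list alone), camera adjusted p = 1.02e-41. Slc2a3 (-0.52 ± 0.09), Slc2a1 (-0.31 ± 0.06) and Slc16a3 (-0.30 ± 0.06) fell. T cell receptor-induced genes were lower: 4 of 27 fell and 23 did not pass (7 adjusted over the list alone), camera adjusted p = 1.21e-09. Tnfrsf4 (-0.47 ± 0.08) and Irf4 (-0.27 ± 0.04) fell. Effector genes were lower: 2 of 27 fell and 25 did not pass (6 adjusted over the list alone), camera adjusted p = 0.000235. The 2 were Prdm1 (-0.35 ± 0.06) and the scarce Ccl4 (from 2.21 ± 0.14 to 1.26 ± 0.30 CPM, -0.81 ± 0.16). Among cholesterol synthesis genes 2 of 27 rose and 25 did not pass (12 adjusted over the list alone), camera adjusted p = 5.78e-12, and adjusted p = 0.172 with an estimated correlation, namely Hmgcs1 (0.29 ± 0.06) and Idi1 (0.27 ± 0.06). The other large changes by rule were rises in Igfbp4 (0.32 ± 0.06), Cpd (0.29 ± 0.06) and Rab37 (0.26 ± 0.06) and falls in Tg (-0.66 ± 0.10), Hilpda (-0.52 ± 0.07), Cd81 (-0.49 ± 0.06) and Tnfrsf8 (-0.48 ± 0.11). The inhibitory receptor list was lower: 1 of 18 rose, 1 fell and 16 did not pass (1 and 4 adjusted over the list alone), camera adjusted p = 0.0162, and adjusted p = 0.183 with an estimated correlation. It was not called without TCA replicate 2 (adjusted p = 0.0661), with values from 0.00276 to 0.183 over the alternatives. Regulatory and IL-17-producing T cell genes were lower as well: 1 of 11 fell and 10 did not pass (2 adjusted over the list alone), camera adjusted p = 0.0272, and adjusted p = 0.105 with an estimated correlation. That member is also in the T cell receptor-induced list. The call was lost without control replicate 1 (adjusted p = 0.0743) or without TCA replicate 1 (0.135) or 3 (0.0621), with values from 0.00866 to 0.135 over the alternatives.

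Camera also called the integrated stress response, endoplasmic reticulum chaperone, fatty acid oxidation, respiratory chain and lysosome lists lower with TCA and the fatty acid synthesis, interferon, and G2 and M phase lists higher. These calls came with medians between -0.06 and 0.06 and at most 1 called member in a list. The camera adjusted p lay between 1.54e-05 and 0.0368, and adjusted p between 0.292 and 0.558 with an estimated correlation. In all, 57 of 13044 tested genes changed, 11 higher and 46 lower (edgeR) with TCA. The count was 6 without TCA replicate 3, 8 without control replicate 2, 14 without control replicate 3 or TCA replicate 1, 114 without control replicate 1, 123 with no filter on low counts, 103 with DESeq2, 14 when fitted on the 6 libraries alone and 138 with the share of reads in exons as a covariate. Of the TCA genes named here, all but Irf4, Tg, Hilpda and Cd81 lost their call in at least 1 of the other fits or with 1 library left out.

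TCDCA at 100 µM lowered glycolysis and hypoxia-responsive genes: 25 of 29 fell and 4 did not pass (26 adjusted over the list alone), camera adjusted p = 4.19e-68. Slc2a3 fell from 342 ± 41.8 to 161 ± 5.8 CPM (-1.09 ± 0.09, edgeR adjusted p = 9.15e-09), and Slc16a3 (-0.81 ± 0.06), Pgk1 (-0.60 ± 0.05) and Pkm (-0.52 ± 0.04) fell with it. Of ranked genes, the largest falls were in Vldlr (-1.99 ± 0.23) and the collagen prolyl hydroxylase gene P4ha2 (-1.96 ± 0.19). P4ha2 lies on chromosome 11, 54100924 to 54131667, plus strand. Next came Pygl (-1.27 ± 0.19), Nrn1 (-1.19 ± 0.09) and Ndrg1 (-1.15 ± 0.11). The largest rises were in Cd244 (0.71 ± 0.08) and Lmna (0.69 ± 0.07), the granzyme gene Gzma (0.67 ± 0.10) and Fam19a3 (0.58 ± 0.12) and Vash1 (0.58 ± 0.07). T cell receptor-induced genes were lower: 7 of 27 fell and 20 did not pass (2 rose and 12 fell adjusted over the list alone), camera adjusted p = 9.77e-07, and adjusted p = 0.125 with an estimated correlation. Irf4 (-0.62 ± 0.04) and Icos (-0.51 ± 0.06) fell. Naive and memory genes were lower: 1 of 24 rose, 9 fell and 14 did not pass (2 and 12 adjusted over the list alone), camera adjusted p = 9.77e-07, and adjusted p = 0.188 with an estimated correlation. Slamf6 (-0.89 ± 0.08) fell. Interferon-stimulated genes were lower: 2 of 33 rose, 14 fell and 17 did not pass (2 and 16 adjusted over the list alone), camera adjusted p = 5.86e-08, and adjusted p = 0.188 with an estimated correlation. Ifit1 (-1.56 ± 0.18) and the scarce Cxcl10 (0.96 ± 0.13 CPM with TCDCA, -1.46 ± 0.22) fell. Of the fatty acid oxidation genes, 6 of 24 fell and 18 did not pass (8 adjusted over the list alone), camera adjusted p = 0.000251, and adjusted p = 0.281 with an estimated correlation. Of the lysosome and autophagy genes, 8 of 32 fell and 24 did not pass (9 adjusted over the list alone), camera adjusted p = 0.00601, and adjusted p = 0.281 with an estimated correlation. Tnf (0.52 ± 0.07) rose and Prf1 (-0.60 ± 0.11) fell. In all, 1712 of 13044 tested genes changed, 663 higher and 1049 lower (edgeR), or 1148 higher and 921 lower after the GC content and length correction. The count was 898 without control replicate 2, 1091 without TCDCA replicate 1 and 1105 without TCDCA replicate 2.

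**Figure D4:**
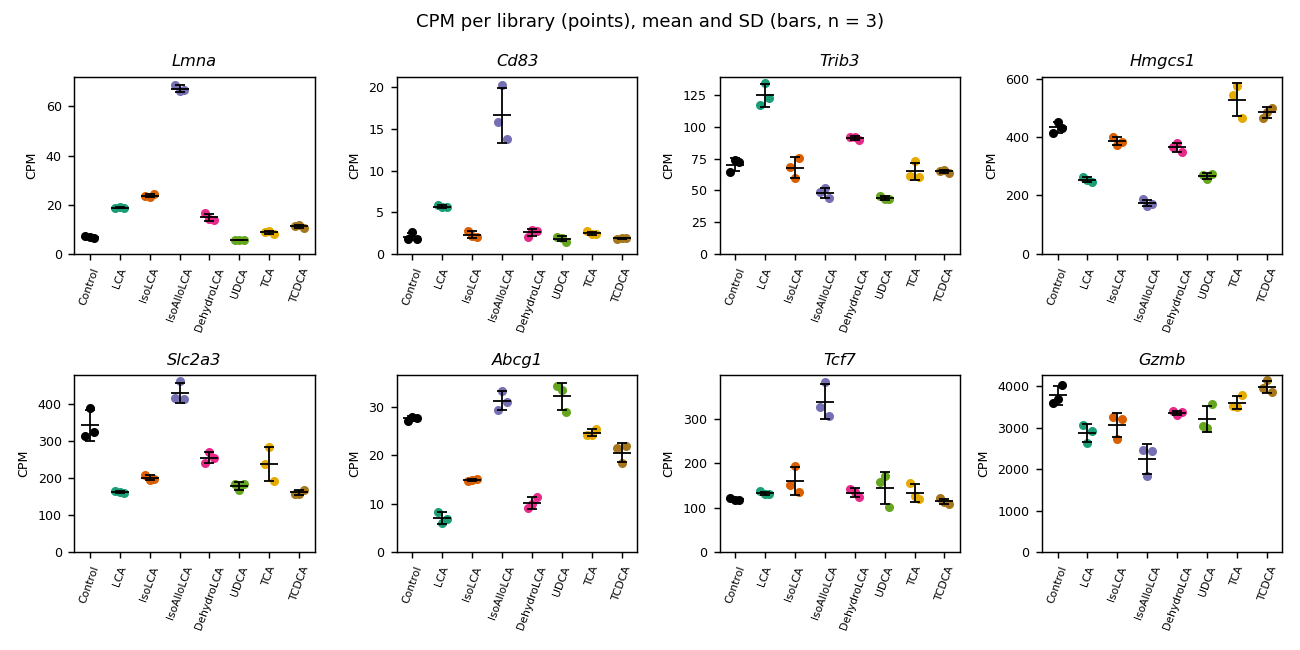
CPM of selected named genes in each of the 24 libraries, 1 point per library, with the mean ± SD of each group of 3. Lmna and Cd83 are highest in IsoAlloLCA, and Slc2a3 is lowest on average in TCDCA.

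NRF2 target genes were not called as a list in the 7 comparisons with control (camera adjusted p between 0.368 and 0.969); with LCA 8 of 26 rose, 9 fell and 9 did not pass (9 and 9 adjusted over the list alone), Nqo1 (0.87 ± 0.18) and Hmox1 (0.53 ± 0.11) among those that rose. Macrophage, dendritic cell and neutrophil genes were not called either (camera adjusted p between 0.0631 and 0.515); with IsoAlloLCA 4 of 8 rose and 4 did not pass (4 adjusted over the list alone). CD4 T cell genes were called lower in TCA by a median of -0.12 (camera adjusted p = 0.0267, and adjusted p = 0.105 with an estimated correlation). That call was lost without control replicate 3 (adjusted p = 0.0711) or TCA replicate 3 (0.0521), with values from 0.00705 to 0.105 over the alternatives. The CD8 chain gene Cd8a stood at 626 ± 10.1 CPM in control and Cd4 at 0.578 ± 0.0483 CPM (SD, n = 3). With IsoAlloLCA Cd4 rose to 0.969 ± 0.188 CPM (0.76 ± 0.24) and Itgax, a gene of dendritic cells, from 0.217 ± 0.0821 to 0.494 ± 0.204 CPM (adjusted p = 0.0186), so a small share of other cells there is not ruled out. Over the 12 comparisons, camera called 153 of 288 list tests, and 39 of these held with an estimated correlation. Against control the calls that held were cholesterol synthesis, fatty acid synthesis, liver X receptor and glycolysis lists with LCA, effector, activation, liver X receptor and bile acid receptor lists with IsoLCA, and cholesterol, bile acid receptor and p53 lists with IsoAlloLCA. They also held for effector, fatty acid synthesis and liver X receptor lists with DehydroLCA, cholesterol and glycolysis lists with UDCA, effector, activation and glycolysis lists with TCA, and the glycolysis list with TCDCA. Il2 and Cyp24a1, fixed in advance, had too few counts to be tested.

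The related acids were next compared at matched dose. IsoLCA differs from LCA in the orientation of the hydroxyl group at carbon 3. At 50 µM, interferon-stimulated genes were lower with IsoLCA than with LCA: 26 of 33 were lower and 7 did not pass (26 adjusted over the list alone), camera adjusted p = 6.19e-28. Isg15 (-1.66 ± 0.13) and Oasl1 (-1.97 ± 0.14) were lower. Integrated stress response genes were lower too: 34 of 39 were lower and 5 did not pass (35 adjusted over the list alone), camera adjusted p = 2.06e-32. Trib3 (-0.88 ± 0.07) and Atf5 (-1.07 ± 0.08) were lower. Cholesterol synthesis genes were higher: 24 of 27 were higher and 3 did not pass (25 adjusted over the list alone), camera adjusted p = 8.59e-27. Hmgcs1 was one of them (0.60 ± 0.06). Liver X receptor targets were also higher: 7 of 12 were higher and 5 did not pass (7 adjusted over the list alone), camera adjusted p = 1.24e-07. The scarce Abca1 (0.66 ± 0.06 CPM in IsoLCA, 0.21 ± 0.03 in LCA, 1.62 ± 0.30) and Abcg1 (1.08 ± 0.10) were higher. Glycolysis genes were also higher: 20 of 29 were higher, 2 were lower and 7 did not pass (22 and 2 adjusted over the list alone), camera adjusted p = 1.25e-13, and adjusted p = 0.132 with an estimated correlation. The largest differences beyond these were in Aldoc (1.42 ± 0.12), Pygl (1.27 ± 0.20), Mt1 (1.18 ± 0.06) and Mt2 (1.15 ± 0.07), higher with IsoLCA, and Rtp4 (-1.62 ± 0.15), Cth (-1.47 ± 0.16) and Cd74 (-1.46 ± 0.10), lower. Camera called 17 of the 24 lists, of which 4 held with an estimated correlation. No difference was called for Gzmb (0.09 ± 0.09, 95% interval -0.08 to 0.27), Pdcd1 (-0.22 ± 0.09, 95% interval -0.40 to -0.03) or Tcf7 (0.27 ± 0.13, 95% interval 0.00 to 0.54). Between IsoLCA and LCA, 3957 of 13044 tested genes differed, 2058 higher and 1899 lower with IsoLCA (edgeR), or 2521 without LCA replicate 2. The GC content and length correction gave 2512 higher and 1435 lower.

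IsoAlloLCA differs from IsoLCA in the configuration at carbon 5. At 50 µM, p53 target and apoptosis genes were higher with IsoAlloLCA: 18 of 24 were higher, 4 were lower and 2 did not pass (18 and 4 adjusted over the list alone), camera adjusted p = 5.83e-16. Bbc3 (1.74 ± 0.08) and Pmaip1 (1.15 ± 0.05) were higher. T cell receptor-induced genes were higher: 17 of 27 were higher, 3 were lower and 7 did not pass (17 and 5 adjusted over the list alone), camera adjusted p = 8.04e-09. Cd69 (1.46 ± 0.06) and Cd44 (0.87 ± 0.04) were higher. Cholesterol synthesis genes were lower: 24 of 27 were lower and 3 did not pass (24 adjusted over the list alone), camera adjusted p = 4.74e-22. Hmgcs1 (-1.15 ± 0.06) and Fdps (-1.09 ± 0.06) were lower. Bile acid receptor, target and transporter genes were higher: 4 of 11 were higher, 2 were lower and 5 did not pass (5 and 2 adjusted over the list alone), camera adjusted p = 0.00568. Naive and memory genes were higher: 17 of 24 were higher, 3 were lower and 4 did not pass (17 and 3 adjusted over the list alone), camera adjusted p = 5.23e-06, and adjusted p = 0.122 with an estimated correlation. Il7r was one of them (1.22 ± 0.05). S phase genes were lower: 28 of 30 were lower and 2 did not pass (28 adjusted over the list alone), camera adjusted p = 2.73e-14, and adjusted p = 0.086 with an estimated correlation. The heat shock list was called lower: 3 of 17 were higher, 11 were lower and 3 did not pass (3 and 11 adjusted over the list alone), camera adjusted p = 0.00261, and adjusted p = 0.222 with an estimated correlation. Its median log2 fold change was -0.25 and its mean, of the other sign, 0.12. The largest differences of ranked genes were in Selp (3.21 ± 0.14), Cd83 (2.86 ± 0.14), Tnfaip3 (2.83 ± 0.12) and Rgs2 (2.57 ± 0.16), higher, and Tnfrsf8 (-1.97 ± 0.14), Fhl2 (-1.73 ± 0.09), Mical2 (-1.61 ± 0.14) and Cxcr3 (-1.46 ± 0.10), lower. Of the 24 lists camera called 15, of which 4 held with an estimated correlation. No difference was called for Prf1 (-0.13 ± 0.11, 95% interval -0.35 to 0.10) or Vdr (-0.11 ± 0.15, 95% interval -0.41 to 0.19). Between IsoAlloLCA and IsoLCA, 7802 of 13044 tested genes differed, 4136 higher and 3666 lower with IsoAlloLCA (edgeR), and 3020 higher and 5034 lower after the GC content and length correction. The DESeq2 Wald test also gave more lower genes, with 3674 higher and 3770 lower.

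DehydroLCA carries a ketone in place of the hydroxyl group of LCA at carbon 3. At 50 µM, glycolysis genes were higher with DehydroLCA than with LCA: 23 of 29 were higher and 6 did not pass (23 higher and 2 lower adjusted over the list alone), camera adjusted p = 4.45e-30. Slc16a3 (0.77 ± 0.06) and Pgk1 (0.50 ± 0.05) were higher. Cholesterol synthesis genes were also higher: 23 of 27 were higher and 4 did not pass (24 adjusted over the list alone), camera adjusted p = 1.72e-28. Hmgcs1 was one of them (0.52 ± 0.06). Liver X receptor targets were higher: 6 of 12 were higher and 6 did not pass (6 adjusted over the list alone), camera adjusted p = 0.000398. For Abca1 no difference was called (-0.32 ± 0.42, 95% interval -1.18 to 0.54). Interferon-stimulated genes were lower: 23 of 33 were lower and 10 did not pass (25 adjusted over the list alone), camera adjusted p = 1.34e-17. Cxcl10 (-1.41 ± 0.15) and Oasl1 (-0.93 ± 0.13) were lower. Integrated stress response genes were lower as well: 1 of 39 was higher, 27 were lower and 11 did not pass (1 and 33 adjusted over the list alone), camera adjusted p = 4.11e-21, and adjusted p = 0.0981 with an estimated correlation. The largest differences of ranked genes were in P4ha2 (1.43 ± 0.19), Aldoc (1.36 ± 0.12), Acvrl1 (1.15 ± 0.11) and Pygl (1.15 ± 0.20), higher, and Cd74 (-1.31 ± 0.10), Kcnq1ot1 (-1.25 ± 0.32), Cth (-1.25 ± 0.16) and Rtp4 (-0.99 ± 0.15), lower. Kcnq1ot1 was not called without LCA replicate 2 (adjusted p = 0.0733). Camera called 16 of the 24 lists, and 4 held with an estimated correlation. No difference was called for Gzmb (0.23 ± 0.09, 95% interval 0.05 to 0.40) or Tcf7 (0.01 ± 0.13, 95% interval -0.26 to 0.29). Between DehydroLCA and LCA, 2317 of 13044 tested genes differed, 1340 higher and 977 lower with DehydroLCA (edgeR). The count was 1189 without LCA replicate 2, 1448 without DehydroLCA replicate 1 and 1377 without DehydroLCA replicate 2. Fitted on the 6 libraries alone, 1796 were higher and 1624 lower.

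UDCA has a hydroxyl group at carbon 7 that LCA lacks. At 50 µM, liver X receptor targets were higher with UDCA than with LCA: 8 of 12 were higher and 4 did not pass (8 adjusted over the list alone), camera adjusted p = 3.39e-16. The scarce Abca1 (1.40 ± 0.33 CPM in UDCA, 0.21 ± 0.03 in LCA, 2.68 ± 0.27) and Abcg1 (2.19 ± 0.09) were higher. Integrated stress response genes were lower: 2 of 39 were higher, 35 were lower and 2 did not pass (2 and 35 adjusted over the list alone), camera adjusted p = 2.38e-61. Trib3 (-1.50 ± 0.08) and Atf3 (-1.26 ± 0.12) were lower. Interferon-stimulated genes were lower: 5 of 33 were higher, 23 were lower and 5 did not pass (6 and 23 adjusted over the list alone), camera adjusted p = 6.26e-24. Oasl1 (-2.43 ± 0.15) and Isg15 (-1.88 ± 0.14) were lower. Respiratory chain genes were higher: 50 of 74 were higher and 24 did not pass (56 adjusted over the list alone), camera adjusted p = 2.57e-18, and adjusted p = 0.222 with an estimated correlation. Endoplasmic reticulum chaperone genes were higher: 19 of 34 were higher, 3 were lower and 12 did not pass (22 and 4 adjusted over the list alone), camera adjusted p = 3.62e-07, and adjusted p = 0.165 with an estimated correlation. Effector genes were higher: 11 of 27 were higher, 6 were lower and 10 did not pass (13 and 6 adjusted over the list alone), camera adjusted p = 0.0149, and adjusted p = 0.159 with an estimated correlation. Gzma (1.17 ± 0.10) and the scarce Xcl1 (3.71 ± 1.40 CPM in UDCA, 0.59 ± 0.04 in LCA, 2.66 ± 0.29) were higher. The largest differences beyond these were in Rap1gap2 (1.55 ± 0.15), Klf2 (1.36 ± 0.16) and Acp5 (1.29 ± 0.08), higher, and Cth (-2.52 ± 0.18), Aldh1l2 (-1.95 ± 0.15) and Ifit1 (-1.95 ± 0.17), lower. Camera called 15 of the 24 lists, and 3 held with an estimated correlation. No difference was called for Hmgcs1 (0.07 ± 0.06, 95% interval -0.06 to 0.19) or Gzmb (0.16 ± 0.09, 95% interval -0.02 to 0.33). Hmgcs1 does not stand for its list, as camera called cholesterol synthesis genes higher with UDCA. The 3 members named by the rule were Dhcr7 (0.41 ± 0.05), Ebp (0.34 ± 0.05) and Cyp51 (0.33 ± 0.06). Fatty acid synthesis, glycolysis, cell cycle and p53 lists were also among those called higher and are not described here. Between UDCA and LCA, 3504 of 13044 tested genes differed, 1934 higher and 1570 lower with UDCA (edgeR), and 2411 higher and 1209 lower after the GC content and length correction.

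TCA has a hydroxyl group at carbon 12 that TCDCA lacks. At 100 µM, glycolysis genes were higher with TCA than with TCDCA: 20 of 29 were higher and 9 did not pass (23 adjusted over the list alone), camera adjusted p = 2.09e-36. Slc16a3 (0.51 ± 0.06) and Pkm (0.32 ± 0.04) were higher. Interferon-stimulated genes were higher: 14 of 33 were higher and 19 did not pass (22 higher and 1 lower adjusted over the list alone), camera adjusted p = 6.53e-22. Ifit1 (1.46 ± 0.18) and Gbp5 (0.41 ± 0.05) were higher. Liver X receptor targets were higher: 2 of 12 were higher and 10 did not pass (3 adjusted over the list alone), camera adjusted p = 0.00432. Naive and memory genes were higher: 5 of 24 were higher and 19 did not pass (11 adjusted over the list alone), camera adjusted p = 9.17e-08, and adjusted p = 0.105 with an estimated correlation. Slamf6 (0.57 ± 0.08) and Il7r (0.33 ± 0.05) were higher. Effector genes were lower: 2 of 27 were higher, 4 were lower and 21 did not pass (2 and 5 adjusted over the list alone), camera adjusted p = 0.00361. Gzma (-0.54 ± 0.09) and Tnf (-0.35 ± 0.07) were lower. The largest differences of ranked genes were in P4ha2 (1.41 ± 0.20), Pygl (1.13 ± 0.19), Aldoc (0.92 ± 0.11) and Nrn1 (0.83 ± 0.09), higher, and Gzma and Tnfsf11 (-0.44 ± 0.10) and Ifngr2 (-0.43 ± 0.08), lower. P4ha2 and Pygl varied between the TCA libraries (12.9 ± 5.03 and 13.4 ± 5.13 CPM). Tnfsf11 was not called without TCA replicate 1 (adjusted p = 0.0739), TCA replicate 2 (0.0772) or TCDCA replicate 2 (0.0815). Camera called 10 of the 24 lists, and 4 held with an estimated correlation. No difference was called for Gzmb (-0.14 ± 0.09, 95% interval -0.32 to 0.03), Hmgcs1 (0.12 ± 0.06, 95% interval 0.00 to 0.24) or Hspa5 (-0.01 ± 0.05, 95% interval -0.11 to 0.08). Between TCA and TCDCA, 471 of 13044 tested genes differed, 346 higher and 125 lower with TCA (edgeR). The count was 185 without TCA replicate 1, 212 without TCA replicate 2, 737 without TCA replicate 3, 246 without TCDCA replicate 1 and 213 without TCDCA replicate 2. The split was 287 higher and 296 lower after the GC content and length correction, and 631 higher and 424 lower with the share of reads in exons as a covariate.

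Responses to the bile acids were compared across genes, which are not independent replicates. The 7 comparisons share the 3 control libraries, too few to divide, so part of any likeness may come from them. The median Pearson r of log2 fold changes over the 21 pairs of acids was 0.489, against 0.50 for simulated unchanged groups with the same controls. The covariance lay above the simulated one in all pairs but IsoAlloLCA and TCDCA (0.00262 against 0.0140, r = 0.0186). The largest differences between observed and simulated covariance were for LCA and UDCA (0.0565 against 0.0138) and UDCA and TCDCA (0.0554 against 0.0138, r = 0.690). UDCA was given at 50 µM and TCDCA at 100 µM. These shared 359 higher and 657 lower genes, against 60.8 and 112.7 expected if the calls of both acids were independent. The shared controls can raise that number by an amount not known here. Simulated unchanged groups shared 0 and 0, but such groups yield few calls by design, so this sets no baseline. Leaving TCA aside, 31 genes were higher and 71 lower in each of the other 6 groups, which share these controls too. Among the lower ones were Acp5 (-1.74 ± 0.08), Scd1 (-1.72 ± 0.10) and Aldoc (-2.05 ± 0.12), with the LCA values given.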

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

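Tests bearing on the glycolysis and Cd74 patterns, and the fits with thinned libraries, GC content and length, or the share of reads in exons, were chosen only after the results were seen.

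Gene lists called in opposite directions in different bile acid groups at the same dose were compared directly, and the difference with the largest median is given for each. The lists were picked because these same libraries had already given calls in opposite directions. A difference in the direction given was therefore likely in advance, and the p-values lend it no separate support. Naive and memory genes were higher in IsoAlloLCA than in LCA by a median of 0.791 (camera adjusted p = 3.19e-07, and adjusted p = 0.0864 with an estimated correlation). T cell receptor-induced genes were higher in IsoAlloLCA than in DehydroLCA by a median of 0.571 (camera adjusted p = 1.11e-05, and adjusted p = 0.127 with an estimated correlation). Integrated stress response genes were higher in LCA than in IsoAlloLCA by a median of 0.88 (camera adjusted p = 1.09e-26, and adjusted p = 0.0716 with an estimated correlation). p53 target and apoptosis genes were higher in IsoAlloLCA than in LCA by a median of 0.949 (camera adjusted p = 8.09e-19, and adjusted p = 0.000171 with an estimated correlation). Interferon-stimulated genes were higher in LCA than in UDCA by a median of 0.888 (camera adjusted p = 6.26e-24, and adjusted p = 0.00467 with an estimated correlation). Lysosome and autophagy genes were higher in IsoAlloLCA than in LCA by a median of 0.448 (camera adjusted p = 8.24e-08, and adjusted p = 0.0716 with an estimated correlation).

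IsoAlloLCA changed 7618 of the 13044 tested genes, and its libraries had the lowest mean share of reads in exons. The count was 7262 with every library thinned to the smallest total, 7765 after correction for GC content and transcript length, and 6683 with the share of reads in exons as a covariate. These values argue against depth, sequence composition or the share of reads in exons as the whole cause, each taken alone. A response of the cells to this acid stays open as a hypothesis, as does a mixture of causes, and a difference in cell survival or in how the libraries were handled may add to it and was not tested.

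Glycolysis and hypoxia-responsive genes were called lower with each of the 7 acids, which share control libraries, though with an estimated correlation the call was lost for IsoLCA (adjusted p = 0.0699), IsoAlloLCA (0.556) and DehydroLCA (0.097). Compared without the controls, 20 of the 29 members were higher in TCA than in TCDCA, which argues against unusual controls as the whole cause with TCDCA. Fewer cycling cells could lower these genes too, but should lower S, G2 and M phase genes at least as far: at most 1 of the 62 was called lower with TCDCA or UDCA, and with each acid but IsoAlloLCA 0 had a log2 fold change as low as the median of the glycolysis list, which argues against this as the whole cause there. With IsoAlloLCA 29 were that low, so it stays open, and as part of the cause it stays open with LCA, where 38 were called lower, and with DehydroLCA, where camera called the G2 and M phase list lower (adjusted p = 0.00392, and 0.498 with an estimated correlation) and 1 gene was called. A metabolic response to the acids, and a difference in oxygen or cell density between cultures, remain untested candidates.

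Cd74 rose in LCA from 4.72 ± 0.383 to 13.1 ± 1.01 CPM (n = 3), and antigen-presenting cells in those libraries would be a candidate source. H2-Ab1 (31.5 ± 2.91 CPM in control, 14.1 ± 0.665 in LCA) and Cd79b, the other genes of such cells above 1 CPM, had a median log2 fold change of -0.854, but the level of H2-Ab1 in control would hide a small share of such cells. H2-Aa (0.349 ± 0.256 CPM in control, 0.569 ± 0.194 in LCA) and H2-Eb1 (0.552 ± 0.151 and 0.490 ± 0.166) stayed under 1 CPM, too low to decide. With IsoAlloLCA Cd74 rose as well (to 10.6 ± 0.906 CPM), and H2-Eb1 rose to 1.67 ± 0.0289 CPM. Such cells, and expression of Cd74 by the T cells as a hypothesis, stay open.

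For each of the 12 comparisons the 10 splits of its 6 libraries are too few for a share under 0.05. In each, 1 split, the real one, gave as many genes as the real count. The real counts were 4765 for LCA, 1284 for IsoLCA, 7618 for IsoAlloLCA, 760 for DehydroLCA, 2599 for UDCA, 57 for TCA and 1712 for TCDCA against control, and 3957 for IsoLCA and LCA, 2317 for DehydroLCA and LCA, 3504 for UDCA and LCA and 471 for TCA and TCDCA, each with a highest other split of 0. For IsoAlloLCA and IsoLCA it was 7802, with a highest other split of 654. These are edgeR counts at an adjusted p under 0.05. At an unadjusted p under 0.05 the highest other split gave 1396 genes for TCA, against 1130 for the real one. For the other 11 comparisons the real split gave the larger number, with the smallest ratio for IsoLCA (2811 against 2558).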

How the results depend on the processing

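The fits with thinned libraries, GC content and length, and the share of reads in exons were chosen after seeing the data. The counts of changed genes for LCA, IsoAlloLCA, UDCA and LCA, and IsoAlloLCA and IsoLCA stayed within 1.5 times under the alternatives run. With 1 library left out, counts ranged from 815 to 1198 for IsoLCA, 400 to 625 for DehydroLCA, 1692 to 2219 for UDCA, 6 to 114 for TCA, 898 to 1628 for TCDCA, 2521 to 3897 for IsoLCA and LCA, 1189 to 2228 for DehydroLCA and LCA and 185 to 737 for TCA and TCDCA. The TCA count was 123 with no filter on low counts, 103 with DESeq2 and 14 on its 6 libraries alone. With the share of reads in exons as a covariate it was 138, that of DehydroLCA 1355 and that of TCA and TCDCA 1055. Camera called 39 list tests with an estimated correlation in place of 153. The causes of these moves were not tested, except that fewer libraries entered some fits. Of 657 calls of named genes, 80 were lost under at least 1 setting fixed in advance, 48 of these only when a library was left out. Mki67, not called in IsoAlloLCA at 0.01, was called lower at -0.154 after GC content and length correction, and Hspa5, lower in IsoAlloLCA than in IsoLCA, was at 0.002 with the share of reads in exons as a covariate, and the cause was not tested. The median correlation between acids ran from 0.506 to 0.574 without each control library. Whether replicate numbers mark a shared preparation stays open. None of the 12 comparisons had each same-number correlation over 0.1, but 15 of 24 libraries correlated best with their own number. Same-number correlations were 0.396, 0.33 and 0.0704 for IsoAlloLCA and IsoLCA, and -0.328, 0.0699 and -0.0041 for IsoAlloLCA and control. With the number as a block the total count rose in each comparison but stayed within 1.5 times, for example 4974 for LCA and 84 for TCA. Higher genes in TCA went from 11 to 22, changes beyond 2-fold in TCA from 1 to 3 and lower genes in TCA against TCDCA from 125 to 189. In the simulated LCA comparison 40% of 1.2-fold changes were called. Far fewer genes were changed there than were called with LCA, which makes the adjusted p stricter. The share called in the real comparisons is therefore not known, and small changes can be missed.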

Other observations

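The added gene lists, the metallothionein genes, the genes shared by the acids and the position of single libraries were chosen for testing or description after the main results were seen.

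Among metal-responsive genes, Mt1, Mt2 and the zinc exporter gene Slc30a1 rose with IsoLCA (log2 fold changes 1.33, 1.83 and 0.80) and with IsoAlloLCA (0.82, 1.05 and 0.40). Mt2 and Slc30a1 also rose with LCA (0.68 and 0.59) and DehydroLCA (0.36 and 0.32), and Slc30a1 with UDCA (0.29). Mt1 and Mt2 fell with TCDCA (-0.29 and -0.33). A small set of genes was lower in each of the 6 groups without TCA. Scd1 stood at 235 CPM in control and Egln3, an oxygen-sensing hydroxylase gene, at 218 CPM. Grin1 (1.54 CPM in control) and Muc2 (2.94 CPM) are scarce genes of the set. Selenbp1 and its near copy Selenbp2 were lower in the 7 groups, with log2 fold changes for Selenbp1 between -1.76 in LCA and -0.75 in TCA. The aryl hydrocarbon receptor gene Ahr was higher in the 6, by 0.60 to 0.87.

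Lists of NF-kB targets, FOXO targets and ribosome biogenesis genes were drawn up as hypotheses, without members of the fixed lists or genes already named. Of the NF-kB targets 14 of 20 rose and 2 fell with IsoAlloLCA (camera adjusted p = 6.12e-11, and adjusted p = 0.00986 with an estimated correlation), and of the FOXO targets 12 of 13 rose (8.32e-08, and 0.0275). These values are consistent with NF-kB and FOXO target activation in IsoAlloLCA, as a hypothesis found on the same data. Of the ribosome biogenesis genes, 33 of 34 fell with IsoAlloLCA (5.83e-16), with an adjusted p of 0.0659 with an estimated correlation. Compared with IsoLCA, 32 of 34 were lower in IsoAlloLCA (2.32e-19, and 0.0439). With LCA 10 of the NF-kB targets rose and 3 fell (6.95e-05), with an adjusted p of 0.121 with an estimated correlation, which leaves a rise over control open as a hypothesis. Compared directly, these targets were lower than in LCA in IsoLCA (14 of 20 lower), DehydroLCA (8 lower, 3 higher) and UDCA (11 lower, 1 higher), with adjusted p of 0.00252, 0.0247 and 0.00657 with an estimated correlation.

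Over the 1712 genes changed by TCDCA, the mean log2 change in the direction of TCDCA was 0.0931, 0.10 and 0.208 in TCA replicates 1, 2 and 3. The libraries of the other acids ran from -0.121 in IsoAlloLCA to 0.376 in TCDCA. These genes were chosen against the same controls, which would shift an unchanged group too, so only the difference between the TCA libraries is read.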
